A study of Mus musculus with 10 samples.

How the data were processed

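RNA from the terminal ileum of male C57Bl6 mice was sequenced as 50-base single-end reads from libraries made with an Illumina TruSeq RNA kit, per the labels' protocols. Whether that kit version marks strand is not given in the sources used here, so reads of a gene and of an overlapping antisense gene are treated as not separable. The 10 libraries fall into 5 from mice after vertical sleeve gastrectomy (VSG) and 5 from sham-operated mice that were pair-fed to them, with replicate numbers taken from the sample titles.

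For each library the authors deposited estimated counts per Ensembl gene, in files whose names speak of RPKM. The values are on the scale of reads: they sum to between 15364651 and 34058181 per library, and 61.18% of them are whole numbers. How fractions of reads were assigned to genes is not given in the sources used here. Genes with near-identical copies, such as the alpha- and beta-globin genes, the defensins of Paneth cells and Acot1 with Acot2, are therefore uncertain as single genes. The second deposited file of each library holds log2 values. These equal the log2 of the same count divided by a factor per library, minus the median of the sham libraries for that gene. The offset between both files was constant within each library (largest SD over genes 3.4e-07), the sham median was 0 within 1e-6 for 100% of genes, and the factors lay within 0.016 log2 units of median-of-ratios factors. DESeq, with no version, and the mouse genome build mm9 are named in the submitters' processing notes. The aligner is not given in the sources used here. No coordinates are printed, because the reference annotation at hand is of another build. Gene symbols are those the files pair with each Ensembl ID. Of 36401 genes, 10315 had no count in any library.

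Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 (R 4.3.3): genes passing filterByExpr, TMM normalisation, the quasi-likelihood F test with surgery as the only term, and Benjamini-Hochberg adjustment with a threshold of 0.05. Normalised CPM values use TMM factors, and log2 CPM values a prior count of 2. Standard errors are the fold change divided by the root of the F statistic. Interval bounds are at the 95% level. Before the data were examined, 38 gene lists (pathways, cell types, gut regions, RNA quality) were fixed. Of their 657 members, 654 were matched to a gene, and Hmgcs1, Mzb1 and Igha were not. Lists with at least 5 genes past the filter, 35 in all, were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, two-sided, adjusted over the lists. With an estimated correlation, camera also takes the 8 residual degrees of freedom, so a call can end for a reason other than the correlation. Library composition was compared with exact two-sided permutation tests over the 252 assignments of the libraries, for which the smallest possible p is 0.0079. The p-values of single genes and of the permutations set a group difference against the spread between these 10 libraries. Those of camera with a preset correlation take the correlation between genes as 0.01. They therefore leave out how the genes of a list vary together between these animals.

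The genes named in the text follow a rule fixed before the data were examined. It takes called genes with a mean of at least 1 CPM, up to 10 per direction by fold change, and the 6 most abundant called genes. It always takes 18 genes of bile acid, hormone and lipid handling, whether called or not, of which 2 are not reported here. It takes up to 4 members of each described list with the lowest adjusted p. Where fewer than 5 genes were called in a direction, it takes the 5 of that direction with the lowest p and a mean of at least 1 CPM. Any other gene named was chosen after its values were seen, and the text says so.

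The procedure was tested on counts simulated from the means and library sizes of the real genes, with 100 genes changed 2-fold and 100 changed 4-fold. With all 10 libraries, 33% of the 2-fold and 84% of the 4-fold changes were recovered among 15483 genes, with 118 calls, of which 1 was false. With the 7 libraries described in the report, 2% and 69% were recovered among 15507 genes, with 77 calls, of which 6 were false. Both runs used the variation per gene estimated from all 10 libraries. The common coefficient of variation was 0.355 in the 10 and 0.3 in the 7, so recovery in the 7 may be understated. A planted gene list was called in both cases, with 0 other lists called in the 10 libraries and 1 false list call in the 7. Genes were simulated independently of each other, so these list counts do not show how often lists of genes that vary together are called falsely.

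Alternatives fixed before the data were examined were other scaling factors (DESeq2 size factors, upper quartile, library totals), other filters, DESeq2 1.42.0, limma-voom with and without sample weights, robust estimation, a replicate block, removal of the 10 most abundant genes, each library left out, an adjusted p of 0.1, camera with an estimated correlation, and fry. Alternatives with the authors' RPKM were planned and not run, since the files used here hold no RPKM values. After the data were seen, 8 alternatives were added: leaving out 3 libraries with high levels of upper small intestine markers, the mean of those markers as a covariate, the deposited log2 values in limma, exact permutation of list means, each list's estimated correlation given to camera as the preset one, the same without each library in turn, an estimated correlation without each library in turn, and composition without each library in turn. For the regional markers, a second list of 12 genes of the upper small intestine and one of 6 ileal genes were also written down. The 12 values had not been looked at, but some of the genes belong to fixed lists whose means per library had. Figures were drawn with matplotlib 3.10.9.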

Results

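The series asked how gene expression in the ileum differs after vertical sleeve gastrectomy, an operation that removes most of the stomach along its greater curvature, in mice made obese with a diet of 60% of energy from fat. Sham-operated mice were pair-fed, that is, given the amount of food that the VSG mice ate. The mice were sampled about 8 weeks after surgery, after an overnight fast and 1 hour after a gavage of 0.5 mL of the liquid diet Osmolite. Terminal ileum was sequenced from 5 mice of each group. Total counts in the VSG libraries were 25790221, 25523402, 15364651, 30401105 and 26396202. In the sham libraries they were 27762274, 32941892, 28614274, 16848364 and 34058181. Correlations of log2 CPM between libraries ran from 0.914 to 0.986, and no library was a copy of another.

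Genes that mark position along the small intestine separated 3 libraries from the other 7, across both groups. The 3 were picked as those above the largest gap in the mean log2 CPM of the fixed upper small intestine list. Higher levels of that list in them therefore follow in part from the choice. In VSG 2, sham 2 and sham 4, Gata4 (ENSMUSG00000021944), a transcription factor of the upper small intestine, stood at 107.2 to 182 normalised CPM, against 1.72 to 6.22 in the other 7 libraries. Lct (ENSMUSG00000026354), which encodes lactase, stood at 1439 to 2587 CPM against 3.69 to 24.9. Both belong to the fixed upper small intestine list and were picked for the text after their values were seen. Of the 8 genes of that list, 5 (Gata4, Lct, Onecut2, Adh6a and Gip) were higher in each of the 3 libraries than in any other, Pdx1 and Cybrd1 overlapped, and Slc40a1, which encodes an iron exporter, went the opposite way, at 3.61 to 13.5 CPM in the 3 libraries against 35.5 to 97.3. Genes of ileal bile acid uptake went the other way: Fabp6 (ENSMUSG00000020405), the ileal bile acid binding protein, stood at 38.8 to 61.6 CPM against 2548 to 6285, and Slc10a2 (ENSMUSG00000023073), the apical bile acid transporter, at 3.87 to 15.1 against 190.2 to 524.3. The first principal component, with 44.9% of the variance of 1000 genes, placed these 3 libraries at 28.46 to 60.98 and the others between -29.87 and -9.56. The 3 libraries make up 1 of 5 VSG and 2 of 5 sham libraries. The mean log2 CPM of the 8 upper small intestine markers was 2.52 ± 1.34 (SD, n = 5) in VSG and 3.36 ± 2.04 (SD, n = 5) in sham, a difference smaller than the spread between animals (exact permutation p = 0.5317).

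**Figure D1:**
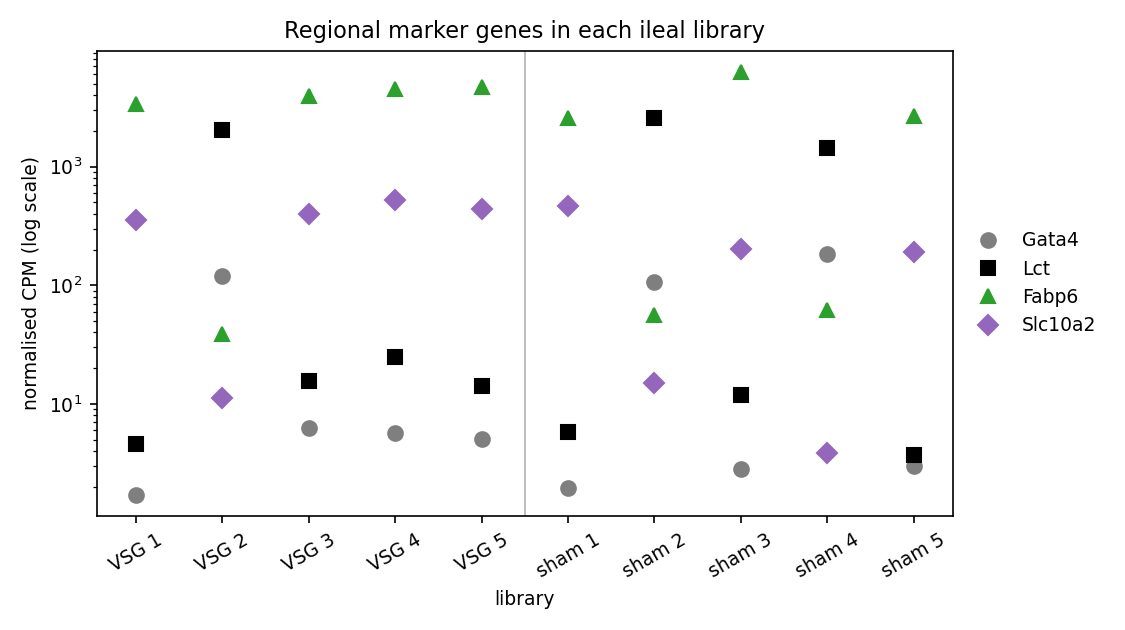
Normalised CPM (log axis) of Gata4, Lct, Fabp6 and Slc10a2 in each of the 5 VSG and 5 sham libraries, 1 symbol per gene. In VSG 2, sham 2 and sham 4, Gata4 and Lct lie above, and Fabp6 and Slc10a2 below, their levels in the other 7 libraries.

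Between VSG and sham, no gene passed the adjusted threshold. The gene nearest to it was Ces1d (ENSMUSG00000056973), a carboxylesterase of lipid metabolism, at 7.07 ± 1.32 CPM in VSG and 18.8 ± 4.28 in sham (SD, n = 5 each), a log2 fold change of -1.42 ± 0.20 (SE) with all 5 VSG libraries below all 5 sham libraries (edgeR adjusted p = 0.268). Next among genes with higher values in VSG was Spsb1, an adaptor of a ubiquitin ligase, at 39.9 ± 4.18 against 24.4 ± 3.04 CPM (log2 fold change 0.70 ± 0.12, edgeR adjusted p = 0.581). Plat, the tissue plasminogen activator, stood at 52.1 ± 16.4 against 25.0 ± 5.68 CPM (log2 fold change 1.06 ± 0.23, edgeR adjusted p = 0.977). The other genes with the lowest p among higher values were 9630028B13Rik, Hemt1 and Gm16683, all below 5 CPM in both groups. Among lower values, Sst, which encodes the hormone somatostatin, stood at 27.5 ± 6.60 against 48.0 ± 9.96 CPM (log2 fold change -0.80 ± 0.19, edgeR adjusted p = 0.977). Sfrp5, a secreted Wnt inhibitor, had a log2 fold change of -1.71 ± 0.42, Adck3 of -0.91 ± 0.24 and A2ld1 of -0.61 ± 0.15. Without VSG 2, sham 2 and sham 4 these were -1.63, -0.48 and -0.59.

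Of 15678 genes tested with edgeR's quasi-likelihood test, 0 were called. At an unadjusted p under 0.05 there were 595 genes, 295 higher and 300 lower in VSG, where 784 are expected by chance. The groups did not overlap for 43 genes above and 43 below, 0.55% of those tested against 0.79% by chance. DESeq2 called 14 genes, with Ces1d the lowest (DESeq2 adjusted p = 8.23e-07), limma-voom called 0 and limma-voom with sample weights called 1, Ces1d (adjusted p = 0.034). Spsb1, Plat, 9630028B13Rik, Hemt1 and Gm16683 were also among the 14 (DESeq2 adjusted p 0.000445 to 0.0353). Sst, Sfrp5, Adck3 and A2ld1 were not. Among genes with p under 0.05, 49.6% were higher in VSG. That share was 30.4% with upper quartile scaling, 32.2% with library totals and 60.3% with the deposited log2 values. Without sham 3 the genes at p under 0.05 numbered 1940, and without VSG 2, 1135, with 0 called in both cases. Without VSG 2, sham 2 and sham 4, a choice made after seeing the data, 0 of 15911 genes were called and 1107 had p under 0.05.

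No gene of bile acid uptake and signalling was called. Fgf15, the ileal hormone that signals bile acid return to the liver, stood at 99.1 ± 95 CPM in VSG and 40.9 ± 45.7 in sham (SD, n = 5 each), a log2 fold change of 1.26 with a 95% interval from -1.33 to 3.86 (edgeR adjusted p = 0.977). For Slc10a2 the log2 fold change was 0.98 (-1.40 to 3.36), for Fabp6 0.52 (-2.16 to 3.20), for Osta 0.44 (-0.85 to 1.73) and for Ostb 0.33 (-0.91 to 1.57). The last pair form the basolateral bile acid exporter. With each library left out the fold change of Fabp6 ran from 0.20 (without sham 2 or sham 4) to 1.30 (without sham 3), that of Fgf15 from 0.76 (VSG 4) to 2.13 (sham 5), of Slc10a2 from 0.68 (sham 2 or sham 4) to 1.76 (sham 1), of Osta from 0.19 (sham 4) to 0.95 (sham 3) and of Ostb from 0.083 (sham 4) to 0.90 (sham 3). The bile acid receptors Nr1h4 and Gpbar1 had log2 fold changes of 0.43 (-0.85 to 1.71) and -0.63 (-1.59 to 0.34), and ran from 0.18 (without VSG 1) to 0.88 (without sham 3) and from -0.90 (VSG 3) to -0.18 (sham 5). Nr0b2, a target of Nr1h4, was too low to be tested. Fgf15, Slc10a2, Fabp6, Osta, Ostb and Nr1h4 were each lower in VSG 2, sham 2 and sham 4 than in any of the other 7 libraries, Fgf15 at 0.276 to 6.14 against 19.7 to 215.8 CPM. With the mean of those markers as a covariate, the fold changes of Fabp6 and Ostb were -0.25 and -0.028. The bile acid list had 9 of 11 members higher and 2 lower, with 0 called over all genes and 0 adjusted over the list alone. Camera called it higher with a preset correlation (adjusted p = 0.0463), and adjusted p = 0.851 with an estimated correlation. It was not called without any of VSG 1, VSG 3, VSG 4, VSG 5, sham 2, sham 4 or sham 5 (adjusted p 0.0593 to 0.229), nor with DESeq2 size factors (0.0577) or the marker covariate (0.248). Without VSG 2, sham 2 and sham 4 together, 10 members were higher and 1 lower, and camera called the list higher (adjusted p = 0.0218). With an estimated correlation in those 7 libraries the adjusted p was 0.438. The log2 fold changes there were 0.89 for Fgf15, 0.59 for Slc10a2, 0.12 for Fabp6, 0.14 for Osta, 0.02 for Ostb, 0.12 for Nr1h4 and -0.84 for Gpbar1.

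**Figure D2:**
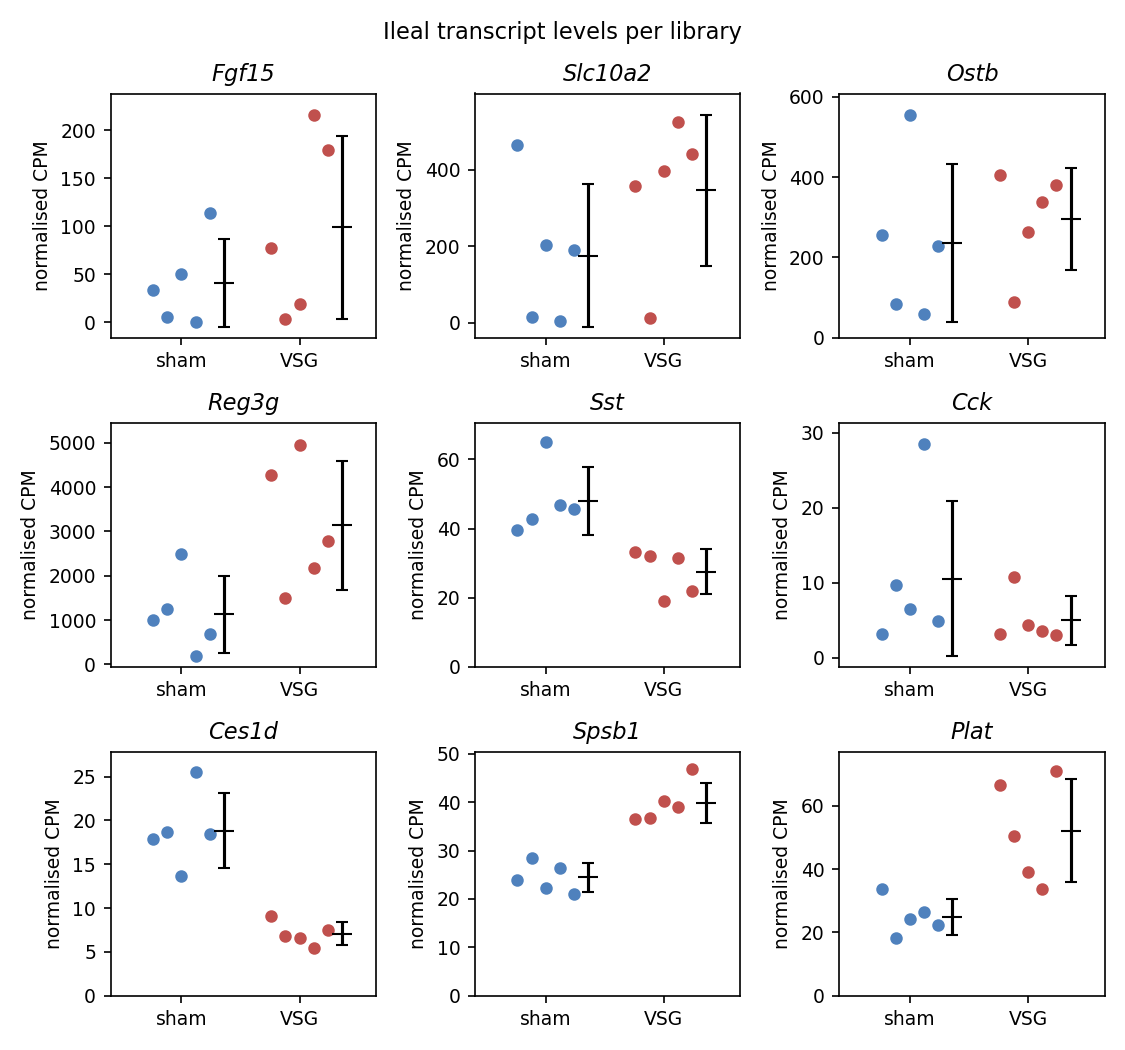
Normalised CPM of 9 genes in each library (points, sham blue, VSG red), with the mean and SD of each group in black, n = 5 per group. Ces1d, Spsb1, Plat and Sst do not overlap between groups, while Fgf15, Slc10a2, Ostb and Cck do.

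Hormone genes of enteroendocrine cells were mostly lower in VSG. Of 20 tested members, 16 were lower and 4 higher, with a median log2 fold change of -0.53. None was called over all genes, and 1, Sst, was called adjusted over the list alone (adjusted p = 0.026). Scg5 and Scg2, proteins of secretory granules, had log2 fold changes of -0.85 ± 0.33 and -0.52 ± 0.24, and Ghrl, which encodes ghrelin, -1.59 ± 0.72. Ghrl stood at 3.96 to 16.6 CPM in VSG 2, sham 2 and sham 4 and at 1.00 to 3.12 in the other 7 libraries, and Cck at 9.65 to 28.5 against 3.04 to 6.48, so their fold changes depend in part on how those 3 libraries fell between the groups. Without the 3 libraries they were -0.81 and -0.43. Among the gut hormones named in advance, Cck had a log2 fold change of -1.07 (-2.39 to 0.24), Gcg -0.42 (-1.34 to 0.51), Pyy 0.23 (-1.40 to 1.86) and Nts 0.21 (-1.06 to 1.47). Without VSG 2, sham 2 and sham 4, Gcg was at -0.78 (edgeR adjusted p = 0.696), Pyy at -0.12 and Nts at 0.04. The values of Pyy and Nts were below 0 without sham 4, at -0.083 and -0.086. Camera called the list lower with a preset correlation (adjusted p = 0.000111), and adjusted p = 0.126 with an estimated correlation, which was 0.022. Its mean log2 CPM was 2.36 ± 0.18 in VSG and 2.76 ± 0.23 in sham (SD, n = 5 each, exact permutation p = 0.0159, adjusted over 35 lists 0.5565).

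Genes of the fixed list of microbe-induced epithelial defence were mostly higher in VSG, and which cells expressed them was not tested. Of 14 members, 10 were higher and 4 lower, with a median log2 fold change of 0.73, and 0 were called over all genes or adjusted over the list alone. Reg3g, an antimicrobial lectin, stood at 3132 ± 1449 CPM against 1125 ± 863.4 (log2 fold change 1.49, 95% interval 0.23 to 2.74, edgeR adjusted p = 0.977). Nos2, the inducible nitric oxide synthase, had a log2 fold change of 2.04 ± 0.82, and S100a9 of 1.48 ± 0.66, at 1.12 against 0.404 CPM. S100a9 stood at 1.95 CPM in VSG 1 and 2.63 in VSG 2. In VSG 3, VSG 4 and VSG 5 it stood at 0.134, 0.510 and 0.364, and in sham at 0.253 to 0.550. Its log2 fold change was 0.77 without VSG 2, sham 2 and sham 4. Camera called the list higher (adjusted p = 0.000111), and adjusted p = 0.16 with an estimated correlation, which was 0.07. Its mean log2 CPM was 4.86 ± 0.48 in VSG and 3.77 ± 0.76 in sham (SD, n = 5 each, exact permutation p = 0.0476, adjusted 0.7408). Nos2 stood at 2.87 to 81.1 CPM in the 3 libraries high in upper small intestine markers and at 46.8 to 420.3 in the other 7.

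All 22 cell cycle genes were lower in VSG, each by a small amount, with a median log2 fold change of -0.21 and 0 called over all genes or adjusted over the list alone. Tk1 had a log2 fold change of -0.25 ± 0.13 and Mcm6 of -0.32 ± 0.18. Camera called the list lower (adjusted p = 4.47e-06), and adjusted p = 0.782 with an estimated correlation. The correlation estimated between its genes was 0.662. Markers of intestinal stem cells were lower for 8 of 10 genes (adjusted p = 0.00905, and adjusted p = 0.782 with an estimated correlation), with Smoc2 at -0.60 ± 0.20 and Lgr5 at -0.51 ± 0.27. That call ended without VSG 5 or sham 1 (adjusted p 0.0898 and 0.065).

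Further lists were called higher with the preset correlation. Cholesterol synthesis genes were higher for 21 of 24 members, Sc5d at 0.20 (-0.07 to 0.46), with adjusted p = 0.00278 and adjusted p = 0.903 with an estimated correlation. The call ended without VSG 1, VSG 3, sham 2 or sham 4 (adjusted p 0.0502 to 0.47) and with the covariate (0.413), and without VSG 2, sham 2 and sham 4 together 12 genes were higher and 12 lower (adjusted p = 0.857). Iron, vitamin and calcium absorption genes were higher for 8 of 13, with S100g, a calcium-binding protein, at 3.55 ± 1.19 and Heph, a copper-dependent iron oxidase, at 0.45 ± 0.17 (adjusted p = 0.0102, and adjusted p = 0.332 with an estimated correlation, which was 0.031). That call ended without sham 1, sham 3 or sham 5 (adjusted p 0.0653 to 0.17). Brush border genes were higher for 12 of 17 with a median log2 fold change of 0.29 and a mean of -0.02, the mean being drawn down by Akp3 at -2.86 ± 1.17, a value of 0.22 without sham 4 (adjusted p = 0.00659, and adjusted p = 0.785 with an estimated correlation). Without sham 5 the call ended (adjusted p = 0.2). Endoplasmic reticulum stress genes were higher for 11 of 12, with Dnajb9 at 0.27 ± 0.12 (adjusted p = 0.00659, and adjusted p = 0.782 with an estimated correlation), a call that ended without VSG 2, VSG 3 or sham 1 (0.0502 to 0.0965) and without the 3 libraries (0.377). Plasma cell markers were higher for 5 of 5, with Derl3 at 0.73 ± 0.30 (adjusted p = 0.00467, and adjusted p = 0.559 with an estimated correlation), and were not called without the 3 libraries (0.0956). None of these lists had a member called over all genes or adjusted over the list alone.

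Further lists were called lower. T cell and intraepithelial lymphocyte markers were lower for 12 of 12 genes, with Ccl5 at -0.77 ± 0.41 (adjusted p = 0.00788, and adjusted p = 0.885 with an estimated correlation). The call ended without VSG 1, VSG 3, sham 1 or sham 3 (0.065 to 0.381) and with the covariate (0.0694). Red blood cell markers were lower for 5 of 5 (adjusted p = 0.00219, and adjusted p = 0.782 with an estimated correlation), with Hba-a2 at -0.61 ± 0.32, a gene whose reads cannot be parted from its near copy, and were not called without sham 3 (0.0971). Fibroblast and matrix genes were lower for 10 of 10, with Col6a1 at -0.38 ± 0.22 (adjusted p = 0.0159, and adjusted p = 0.885 with an estimated correlation), a call that ended without VSG 1, VSG 2, sham 1, sham 2 or sham 5 (0.0569 to 0.198) and without the 3 libraries (0.122). Ribosomal protein genes were lower for 78 of 80 (adjusted p = 0.0373, and adjusted p = 0.904 with an estimated correlation). They were not called without VSG 2 or VSG 3 (0.44 and 0.523) or with the replicate block (0.143), and without sham 3 the direction turned (adjusted p = 4.59e-07, higher). Oxidative phosphorylation genes were lower for 74 of 75 (adjusted p = 0.0415, and adjusted p = 0.904 with an estimated correlation). Their call ended without VSG 1 or VSG 4 (0.0849 and 0.161) and with the replicate block (0.145), and their direction turned, with no call, without sham 3 or sham 4 (0.0792 and 0.347), without the 3 libraries (0.551) and with the covariate (0.68). None of these lists had a member called over all genes or adjusted over the list alone.

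**Figure D3:**
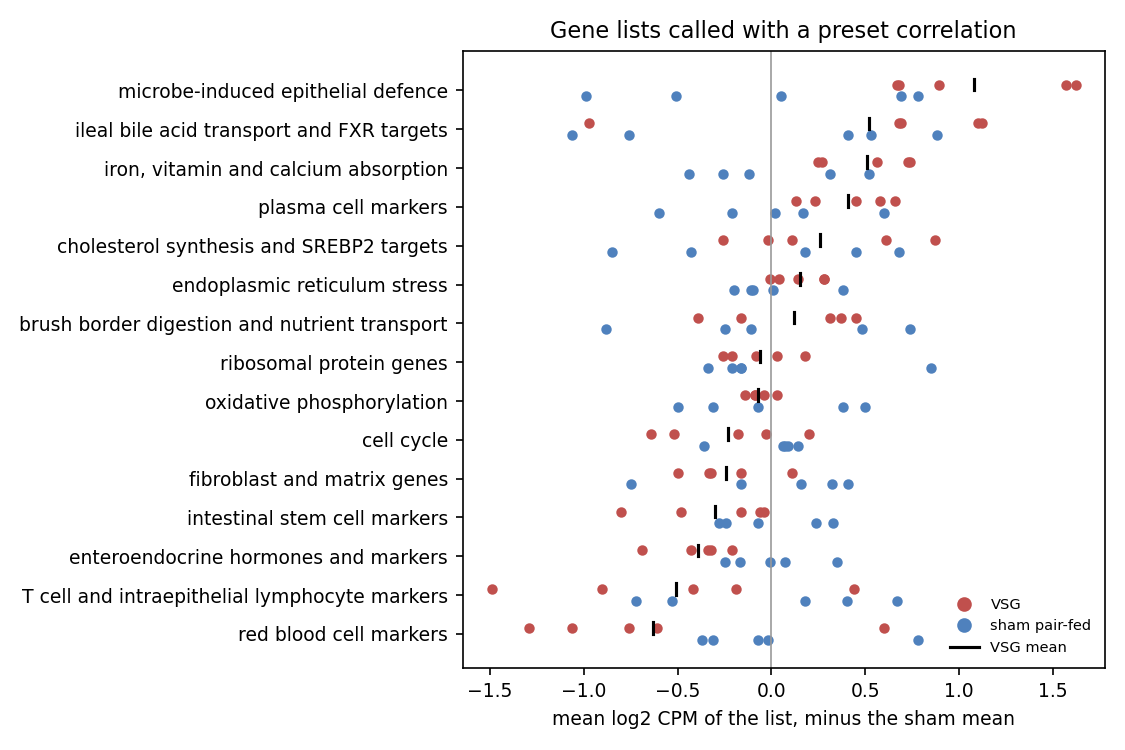
Mean log2 CPM of each of the 15 lists called with a preset correlation, per library, minus the mean of the sham libraries. Points are libraries (red VSG, blue sham), black bars the VSG mean, and the groups overlap for every list shown.

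Camera called 15 of 35 lists with a preset correlation, 7 higher and 8 lower. With an estimated correlation it called 0, fry called 0 (lowest adjusted p = 0.283), and the exact permutation of list means called 0. The permutation could hardly have called any: a single list at the smallest possible p would have an adjusted p of 0.2778, and 6 lists would have to reach it. With each list's estimated correlation given to camera as the preset one, a test chosen after the data were seen, 2 lists were called, enteroendocrine (adjusted p = 0.00169) and microbe-induced genes (adjusted p = 0.0112). Those calls ended without sham 3 (0.138 and 0.0983), and the second also without VSG 2, sham 1 or sham 2 (0.067 to 0.0737). Lists that were not called included lipid absorption (11 of 21 genes higher, adjusted p = 0.062), interferon-induced genes (21 of 29 lower, 0.056), B cell and lymphoid follicle markers (9 of 11 higher, 0.056), fatty acid oxidation (12 of 22 higher, 0.384), fatty acid synthesis (0.78), glucose transport (0.384), Paneth cells (11 of 12 lower, 0.231), goblet cells (0.743), tuft cells (0.673) and smooth muscle (10 of 10 lower, 0.514). Apoa4, which encodes a chylomicron apolipoprotein, stood at 6331 ± 7152 CPM in VSG and 8124 ± 10920 in sham, Cpt1a had a log2 fold change of 0.09 (-0.32 to 0.50) and Pck1 of -0.54 (-2.71 to 1.63). The direction of Apoa4 and Pck1 changed with limma-voom or the replicate block, and also without the 3 libraries high in upper small intestine markers. Apoa4 stood at 16086 to 23401 CPM in them against 206.3 to 9189 in the other 7, and its log2 fold change of -0.37 was 3.24 without them. Pck1 stood at 318.8 to 669.4 CPM against 22.8 to 113.7, with a log2 fold change of 1.27 without them and 0.54 without sham 2. Enteric neuron and glia markers (11 of 12 lower, 0.56), endothelial markers (8 of 8 lower, 0.213), adipocyte markers (9 of 10 lower, 0.891), macrophage and dendritic cell markers (8 of 11 lower, 0.673), xenobiotic metabolism (14 of 18 lower, 0.383), MHC class II genes (8 of 11 lower, 0.718), the circadian clock (10 of 16 higher, 0.31), the integrated stress response (9 of 12 lower, 0.528), immediate early genes (10 of 18 higher, 0.305) and upper small intestine markers (6 of 7 lower, 0.483) were not called either.

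Of these 20 lists, 12 were called with the preset correlation when a single library was left out. Lipid absorption genes were called without VSG 1, VSG 3, sham 2 or sham 4 (adjusted p 4.52e-05 to 0.0443), and B cell markers without VSG 1, VSG 3, sham 1, sham 3 or sham 5 (0.000194 to 0.036). Over all libraries 9 of 11 B cell markers were higher in VSG. Without VSG 2, sham 2 and sham 4 together the list was called lower (0.00365, and 0.562 with an estimated correlation). Interferon-induced genes were called without VSG 2 (6.75e-07) or sham 2 (5.59e-05). Paneth cell markers were called without VSG 3 (0.0402) or sham 4 (1.09e-11), the library with their lowest mean. Without sham 4, fatty acid oxidation (0.000849) and glucose transport genes (0.0138) were called as well. Without sham 3, smooth muscle (0.00188), enteric neuron (0.00149) and endothelial markers (0.000682) were called lower, the last also without VSG 2 (0.0264). Circadian clock (0.0335) and immediate early genes (0.00196) were called without sham 2, and xenobiotic metabolism without sham 5 (0.000974). With the replicate block, lipid absorption genes (0.00857), enteric neuron (0.0169) and endothelial markers (0.0497) were called. Over all libraries the adjusted p of the 20 lists with an estimated correlation ran from 0.903 to 0.955. With an estimated correlation and each library left out, a test chosen after the data were seen, 0 lists were called (lowest adjusted p = 0.074).

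Of 24 measures of library composition, the lowest exact permutation p was 0.1032, for plasma cell markers, higher in VSG at 4.02 ± 0.23 against 3.61 ± 0.45 log2 CPM (n = 5 each). Adjustment over these measures decides little, since a single measure at the smallest possible p would have an adjusted p of 0.1905. The enteroendocrine list was filed as a pathway and is not among the 24. Its exact permutation p was 0.0159, adjusted over 35 lists 0.5565. Markers of B cells and lymphoid follicles varied from -0.71 to 3.99 mean log2 CPM between libraries, and those of smooth muscle from 4.40 to 8.10 (exact permutation p = 0.5714 and 0.8095 between the groups). Sham 3 had the highest B cell value and the lowest smooth muscle value.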

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

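In this part, the test of bile acid receptor signalling and the test of the surgery group were chosen after the result was seen. A sample far from the other 4 of its group was found for 12 of 104 sets of 5 values, 11.5% where chance gives about 5%, and 7 of the 12 concern VSG 2. The rule finds a single far sample, so 2 far samples of a group can hide each other. Fabp6, for instance, stood at 56.1 CPM in sham 2 and 61.6 in sham 4, and neither was flagged. The sets also share libraries, so the 5% is a rough guide. In VSG 2 the log2 CPM was lowest for Slc10a2 (3.50 against 8.48 to 9.03, gap over range 0.9), Fabp6 (5.28 against 11.72 to 12.19, 0.932), Ostb (6.49 against 8.04 to 8.66, 0.714), Pyy (3.22 against 5.20 to 5.59, 0.835), Nts (5.51 against 6.56 to 6.72, 0.865) and Cpt1a (7.18 against 7.97 to 8.09, 0.868), and the mean of the upper small intestine markers was highest (4.85 against 1.41 to 2.20, 0.77). In sham 4, Nts was lowest (2.32 against 6.14 to 7.05, 0.806). In sham 3, the ribosomal protein mean was highest (9.09 against 7.90 to 8.08, 0.849) and the endothelial mean lowest (2.77 against 4.07 to 4.19, 0.915). The adipocyte mean was lowest in VSG 4 (1.22 against 2.67 to 3.07, 0.784). The pancreatic acinar mean was lowest in sham 1 (-1.97 against -1.81 to -1.76, 0.762), at a level close to no reads.

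The libraries VSG 2, sham 2 and sham 4 stood apart in regional markers. They came from both groups, 1 of 5 VSG and 2 of 5 sham libraries (two-sided exact Fisher p = 1), but with 3 libraries the smallest p this test can give is 0.167, so a link with surgery stays open. For tissue taken further up the small intestine, 6 of 12 genes of the second upper small intestine list were higher in each of the 3 libraries than in every other library, which just meets the bound of 6 set beforehand, where 5.54% of all tested genes were higher in each of the 3. Rbp2, Slc2a2, Mogat2, Ckmt1, Khk and Creb3l3 were these genes, while Slc2a5, Npc1l1, Gsta1, Ccl25, Slc5a1 and Reg1 overlapped, and of 6 ileal genes Pyy and Clec2h were below and 4 overlapped. Lower bile acid receptor signalling within the same region, as the whole cause, would leave genes of the upper small intestine in place only if they do not respond to the receptor. The same 6 of 12, from a list that took no part in picking the libraries, cannot decide on it. The bound for that test was written with the count known. Nr0b2, the receptor target, was higher in the 3 libraries at 0.70 to 5.75 CPM against 0.078 to 0.405, levels too low to decide. Whether any of the 12 genes respond to the receptor was not tested, so lower signalling as the whole or a part of the pattern stays open. Against a site further up, Slc40a1 of the fixed upper small intestine list was lower in the 3 libraries, at 3.61 to 13.5 against 35.5 to 97.3 CPM. That 5 of the 8 genes of that list were higher is no test of the site, since the mean of the list picked the 3 libraries. A sampling site further up the intestine is therefore a candidate explanation and a hypothesis, and a shift of regional identity in the ileum itself was not tested.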

How the results depend on the processing

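In this part, the fits without VSG 2, sham 2 and sham 4, with the regional marker covariate, with the deposited log2 values, the permutation of list means, the estimated correlations given as preset (also with a library left out), estimated correlations with a library left out, and composition without each library were chosen after the data were seen, and the RPKM alternatives were not run. No gene was called with edgeR under any scaling, filter, block or left-out library tried. DESeq2 called 14 genes and limma-voom with sample weights called 1; the cause was not tested. Genes at p under 0.05 numbered 595, and 1015 with no filter, where more genes were tested, 2409 with sample weights, the cause of which was not tested, 1107 without the 3 libraries, and 399 to 1940 with each library left out. Camera called 15 lists, 11 to 16 with each library left out, and 0 with an estimated correlation (over all libraries and with each left out), with fry or with permutation, where a single list could not pass. With the estimated correlations given as preset it called 2, and 0 to 3 with each library left out. The lowest composition p was 0.1032, and 0.0079 to 0.1746 with each library left out. Its lowest value, for red blood cell markers without VSG 4, is the smallest that 9 libraries can give, and is 0.1905 after adjustment. The labels do not say whether the replicate numbers pair the animals. The deviations of same-numbered libraries from their group means correlated at 0.04, 0.18, -0.05, -0.32 and -0.07. Such correlations cannot show which mice were paired, so this stays open. With the replicate block, 0 genes were called, 408 had p under 0.05 and 16 lists were called: ribosomal protein (0.143) and oxidative phosphorylation genes (0.145) lost their call, and lipid absorption genes (0.00857), enteric neuron (0.0169) and endothelial markers (0.0497) gained one.

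Of 84 genes followed, 14 changed sign in some setting, in 34 of 2013 values, none of them past the threshold; the cause was not tested. Apoa4 had log2 fold changes of 0.93 with limma-voom, 1.15 with sample weights, 1.17 with the replicate block, 3.24 without the 3 libraries, 2.24 with the covariate, 1.01 with the deposited log2 values and -1.23 to 0.56 with each library left out. Pck1 had 0.03, 0.10, 0.06, 1.27, 0.60, 0.082 and -1.47 to 0.54 in the same order. Akp3 had 0.04 with sample weights, 0.72 without the 3 libraries, 0.31 with the covariate and -3.16 to 0.22 with each library left out. With the covariate, Fabp6 had -0.25, Ostb -0.028, Pyy -0.078 and Nts -0.035. Pyy had -0.12 without the 3 libraries and -0.083 to 0.80 with each library left out, and Nts -0.086 to 0.49. With sample weights, Rps4y2 had 0.03, Rps15a 0.017, Ndufb2 0.009 and Ndufa1 0.047. With each library left out, Rps15a had -0.36 to 0.068, Rpl12 -0.34 to 0.059 and Rps6 -0.28 to 0.026. Creld2 had -0.028 without the 3 libraries.

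A list without a call has no direction in the text, so it counts as turned only where a setting called it the other way. On that rule 9 of 630 list values turned, 101 lost a call and 37 gained one, and 52 more changed direction without a call. Without the 3 libraries, cholesterol synthesis (0.857) and oxidative phosphorylation (0.551, and 0.68 with the covariate) turned without a call, and xenobiotic metabolism was called higher (0.00128, and 0.514 with an estimated correlation), MHC class II lower (0.00396, and 0.562) and B cell markers lower (0.00365, and 0.562). With each library left out, adjusted p ran from 4.59e-07 to 0.523 for ribosomal protein genes and from 8.95e-10 to 0.347 for oxidative phosphorylation. The share of counts in the most abundant genes differed by -0.455 percentage points for 10 genes and 0.0208 for 50. In the simulated data with 5 libraries per group, 33% of 2-fold and 84% of 4-fold changes were recovered. These data used the variation per gene of all 10 libraries, with genes drawn independently of each other. Depth was not varied, so what limits recovery in the real data was not tested.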

Other observations

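In this part, the tests without VSG 2, sham 2 and sham 4 and the tests of what underlies the list calls were chosen after the data were seen, and so were the genes named in the next 2 paragraphs outside the fixed rule. With those libraries left out, 4 VSG and 3 sham libraries remained. No gene passed the threshold with edgeR, and 2 lay under an adjusted p of 0.1, Slc30a10 and Slc28a2. Slc30a10, a manganese exporter, stood at 167.1 ± 51.5 CPM in VSG and 24.5 ± 4.93 in sham (log2 fold change 2.78, edgeR adjusted p = 0.0855). Slc28a2, a nucleoside transporter, stood at 204.6 ± 50.6 and 52.0 ± 7.09 CPM (1.98, edgeR adjusted p = 0.0855). Over all 10 libraries their log2 fold changes were 1.72 and 0.92 (edgeR adjusted p = 0.977 for both). Nt5e, which makes adenosine outside cells, had a log2 fold change of 1.70 (edgeR adjusted p = 0.118). Among lower values were Gbp2, an interferon-induced GTPase, at -1.23 and Agt, angiotensinogen, at -0.99 (edgeR adjusted p = 0.213 each), and Reg4 at -1.94 (edgeR adjusted p = 0.351). In the simulated data for 7 libraries, which used the variation estimated from all 10, 69% of 4-fold changes were recovered.

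Several lists that were not called over all 10 libraries were called with a preset correlation in these 7. Interferon-induced genes were lower for 28 of 29 members (adjusted p = 1.83e-14, and adjusted p = 0.129 with an estimated correlation). Paneth cell markers were lower for 12 of 12 (5.5e-13, and 0.299 estimated), with a median log2 fold change of -1.57. Lipid absorption genes were higher for 19 of 21 (4.87e-10, and 0.299 estimated) and fatty acid oxidation genes for 22 of 22 (1.52e-08, and 0.299 estimated). Other lists moved beside them. Brush border genes were higher for 17 of 17 (2.69e-06, and 0.469 estimated) and immediate early genes for 14 of 18 (0.0104, and 0.469). Cell cycle genes were lower for 22 of 22 (5.95e-08, and 0.464), stem cell markers for 8 of 10 (0.00385, and 0.514) and ribosomal protein genes for 79 of 80 (6.82e-05, and 0.706). A changed share of cell types was thus not separated from a change within cells. Markers of several immune cell types were lower too, T cells for 12 of 12 (median log2 fold change -0.92, 0.464 estimated), B cells for 11 of 11 (-0.63, 0.562 estimated), MHC class II genes for 11 of 11 (-0.57, 0.562 estimated) and macrophages and dendritic cells for 9 of 11 (-0.42, 0.312 estimated), while plasma cell markers were higher for 4 of 5 with no call (0.37, adjusted p = 0.0956, and 0.562 estimated), so a smaller share of immune cells was not separated from lower interferon signalling. In the simulated data for 7 libraries, where genes were drawn independently of each other, 1 list besides the planted one was called. In all, 20 lists were called, 9 higher and 11 lower, and 0 with an estimated correlation.

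Of the 15 lists called with a preset correlation, 12 had an estimated correlation of at least 0.1, and for these the call may follow from genes that vary together between animals: 0 of the 12 were called with their estimated correlation given as the preset one. The other 3 had low estimated correlations, 0.022 for enteroendocrine, 0.031 for iron and vitamin absorption and 0.07 for microbe-induced genes. Their calls ended in the test that estimates the correlation (adjusted p 0.126, 0.332 and 0.16), which also has fewer degrees of freedom, but 2 of the 3 were called with that correlation given as the preset one (adjusted p 0.00169 and 0.0112, and 0.0894 for iron and vitamin absorption). These calls ended in turn without sham 3 for enteroendocrine (0.138) and without VSG 2, sham 1, sham 2 or sham 3 for microbe-induced genes (0.067 to 0.0983), so the explanation stays open for them. Chance in how animals fell into groups could not be excluded either, since 46 of 100 splits of the 10 libraries, the real one included, called as many lists, with 15 in the real split and 26 in the highest other. Whether the 3 libraries high in regional markers account for the calls stays open: 10 of the 15 lists were called in the same direction without them, between the bounds set for and against. A biological difference due to surgery stays open as well.

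With 0 called genes in the real split, all 100 splits gave at least as many whatever the cause, so that count decides nothing; the highest other split gave 4. For genes at p under 0.05 chance could not be excluded: 52 of 100 splits gave at least the 595 of the real split, and the highest other gave 3809. That number, several times the real one, points to a structure of the samples. In that split VSG 2, sham 2 and sham 4, the libraries that stood apart in regional markers, were on the same side. It was the real split with VSG 2 and sham 3 exchanged, so a part played by sham 3 was not separated. The 19 splits with VSG 2, sham 2 and sham 4 together gave 778 to 3809 genes (median 1715), and the other splits, the real one aside, 127 to 2451 (median 498.5). Libraries picked for standing apart make such a difference expected, so it is no test of what the structure is.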
